A study of Homo sapiens with 6 samples.

How the data were processed

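RNA-seq libraries of the human papillary thyroid cancer line TPC1 were analysed, 3 from cells with a vector and 3 from cells overexpressing TFCP2L1. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a VAHTS Universal kit for RNA-seq. Whether the libraries kept strand is not given in the sources used here, so reads of a gene and of an overlapping antisense gene could not be told apart. The submitters' processing notes name fastp, HISAT2 and HTSeq, without versions, and the genome build GRCh38.p13.

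The authors deposited a table of raw read counts for 21173 genes, each with at least 1 read in some library, and a table of FPKM values for the same genes. Dividing count by FPKM and library total gave a single gene length, within 0.001%, for all 21173 genes. The deposited FPKM values were therefore the counts divided by gene length and library total, with no further normalization, and they gave no independent measurement. The 6 columns were matched to samples by the group and replicate number in their names. Library totals ran from 37928516 to 38987434 reads. Gene symbols were matched to GENCODE v29 on GRCh38 for positions, overlaps and GC content, and 17551 of 21173 symbols matched. Positions come from that annotation, not from the tables.

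Counts as deposited were tested with edgeR 4.0.16 (R 4.3.3): genes were kept by filterByExpr (14431), libraries were scaled by TMM, and the 2 groups were compared by the quasi-likelihood F-test with robust dispersion, two-sided, in 1 fit of all 6 libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. Levels are CPM, reads scaled to library size after TMM, except for TFCP2L1 and for shares of reads, which use the library total. The common dispersion was 0.0116, a biological coefficient of variation of 10.8%. A gene with 0 reads in a group was given a fold only as a bound against 3 reads over that group.

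A total of 39 gene lists had been fixed: pathways studied in thyroid cancer cells, factors and tissues linked to TFCP2L1, stress and RNA quality lists and markers of other cell types. The 37 with 5 or more tested members were compared with all other genes by limma 3.58.1 camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation. The rotation test fry, which asks only whether a list's genes move on balance in 1 direction, was run beside it. Named genes were set by a rule: TFCP2L1; the 13 highest and 13 lowest fold changes among called genes with a symbol, a mean of at least 2 CPM in the higher group and no overlap between the 3 libraries of each group; and up to 4 members of each list, those called with the largest change, or the 2 with the smallest p where fewer than 2 were called. For the CP2 and grainyhead list, all tested members were given. The groups, lists, tests, naming rule and most alternatives were set before the data were examined.

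Alternatives covered other scalings, filters, DESeq2 1.42.0, limma-voom, limma on the deposited FPKM values with pseudocounts of 1 and 0.1, a replicate block, a test against a 1.2-fold change and leaving out each library. Simulated counts with the real means, library sizes and spread were run through the same edgeR comparison over 14393 genes. It recovered 28.6% of genes changed 1.3-fold, 62.0% at 1.5-fold, 70.8% at 2-fold and 100% at 4-fold. In that simulation 16 calls were false, 9.64% of calls, above the nominal 5%. Camera called the simulated raised list and 0 of 30 unchanged lists. Genes were simulated independently of each other, so this does not test the preset correlation on which the list calls below depend. Replicate libraries of a group differed by more than sampling noise, with a chi-square per gene of 7.80 to 45.5, so none was a copy of another. This spread can arise in library preparation alone and does not show separate cultures. Intervals cover counting error only.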

Results

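RNA was sequenced from TPC1 cells, a human papillary thyroid carcinoma line that carries a RET fusion. The 6 libraries were 3 of vector cells and 3 of cells overexpressing TFCP2L1, a transcription factor of the CP2 and grainyhead family known from naive pluripotent cells and kidney collecting duct. Library totals were 37928516, 38249193 and 38185880 reads in vector cells and 38323482, 38987434 and 38213520 in TFCP2L1 cells, and 17805 to 18102 genes had a read. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The first principal component of log2 CPM, with 44.2% of the variance, separated the groups. Mitochondrially encoded genes took 5.66% ± 0.910 (SD, n = 3) of reads in vector cells and 6.19% ± 1.25 in TFCP2L1 cells, with the highest shares in vector replicate 2 (6.72%) and TFCP2L1 replicate 3 (7.59%).

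The overexpressed gene was checked first. TFCP2L1 (ENSG00000115112.7; GRCh38 chromosome 2, 121216587 to 121285207, minus strand) had 0, 0 and 1 read in the vector libraries and 13578, 13885 and 12333 reads in the TFCP2L1 libraries, a mean of 344 ± 18.8 CPM (SD, n = 3). The ratio of summed reads was 39400, with an exact 95% counting interval of 7070 to 1556000. The exact two-sided permutation test of CPM gave p = 0.1, the smallest that 3 against 3 libraries allow, and edgeR's quasi-likelihood test gave an adjusted p of 1.24e-15. Among relatives in the CP2 and grainyhead list, TFCP2 was at 29.6 ± 1.03 and 30.3 ± 1.21 CPM and UBP1 at 109 ± 5.06 and 116 ± 9.52 CPM in vector and TFCP2L1 cells. GRHL1 rose from 3.28 ± 0.698 to 5.19 ± 0.499 CPM (edgeR adjusted p = 0.0367), a call lost without vector replicate 1 (0.174) or 3 (0.128) or TFCP2L1 replicate 1 (0.132) or 2 (0.0514). Adjusted over the list alone, 1 of the 3 tested members was called.

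The comparison of TFCP2L1 with vector cells asked which transcripts differ when TFCP2L1 is overexpressed in thyroid cancer cells. Interferon-stimulated genes were prominent among the largest rises. IFITM1, a membrane protein that restricts virus entry, rose from 0.671 ± 0.0171 to 25.2 ± 2.78 CPM, a log2 fold change of 5.23 ± 0.19 (SE). IFI44L rose from 6.71 ± 0.148 to 63.2 ± 3.53 CPM (3.24 ± 0.10). Some genes of secreted immune proteins were among the largest falls. The chemokine gene CCL3L3 fell from 178 ± 38.7 to 11.7 ± 0.683 CPM (-3.92 ± 0.15). SLPI, a secreted inhibitor of leukocyte proteases, fell from 29.1 ± 5.08 to 4.06 ± 0.955 CPM (-2.84 ± 0.17). By edgeR's quasi-likelihood test, 676 of 14431 tested genes were higher in TFCP2L1 cells and 1016 were lower, 1692 in all. Most changes were small, with a median absolute log2 fold change of 0.50, and 338 called genes changed at least 2-fold, 91 higher and 247 lower. The 3 libraries of each group did not overlap for 4331 of the tested genes, against 10% of genes by chance. The counts depended on single libraries, in both directions: 294 higher and 675 lower without vector replicate 1, 313 and 654 without vector replicate 3, and 763 and 1108 without TFCP2L1 replicate 3.

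**Figure D1:**
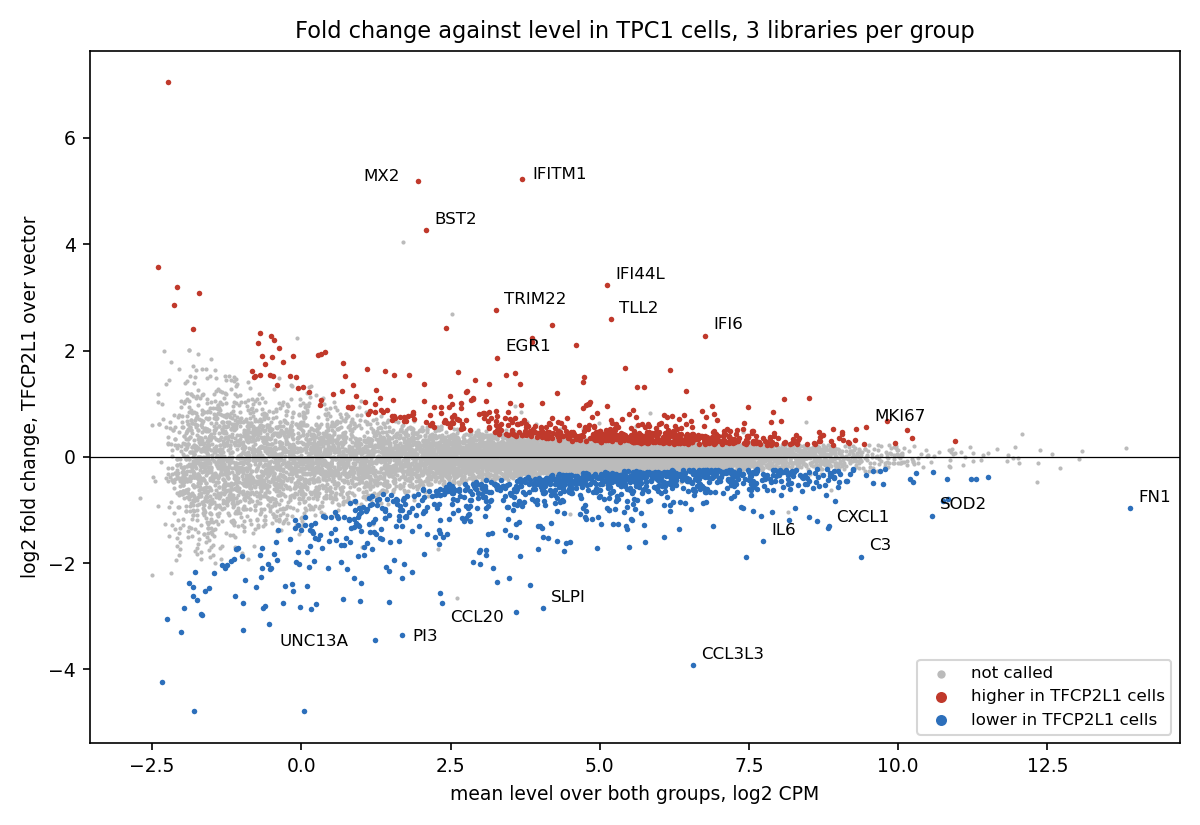
Each point is a tested gene, with the mean level over both groups (log2 CPM) on the x axis and the log2 fold change of TFCP2L1 over vector cells (3 libraries each) on the y axis; TFCP2L1, XAF1 and TMEM52B are left out because a group had almost no reads. Red points are genes called higher and blue points genes called lower by edgeR, with MX2 at 5.19, IFI44L at 3.24 and CCL3L3 at -3.92.

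Other genes among the 13 highest fold changes were MX2 (5.19 ± 0.32), BST2 (4.27 ± 0.27), TRIM22 (2.75 ± 0.15), IFI27 (2.49 ± 0.33), CMPK2 (2.42 ± 0.20), IFI6 (2.28 ± 0.13) and IRF7 (2.24 ± 0.14), all known to be induced by interferon. The metalloprotease gene TLL2 (2.59 ± 0.11), the sulfotransferase gene SULT1C2 (2.16 ± 0.13), the phosphodiesterase gene PDE2A (2.10 ± 0.10) and the phospholipase gene PLCD4 (1.98 ± 0.33) completed them. At the other end stood UNC13A (-3.45 ± 0.29), the protease inhibitor gene PI3 (-3.35 ± 0.28), CCL3 (-2.92 ± 0.19), ANXA8L1 (-2.78 ± 0.37) and CCL20 (-2.76 ± 0.25). TRIML2 (-2.72 ± 0.32), KRT34 (-2.68 ± 0.37), TNFSF14 (-2.56 ± 0.21), CLEC4E (-2.41 ± 0.15) and COL9A2 (-2.38 ± 0.31) were also among the 13 lowest. The edgeR adjusted p of these genes ran up to 0.00478, that of IFI27. CCL3 with CCL3L3 and ANXA8L1 with ANXA8 are near-identical copies, and 32.5% of the exon bases of IFITM1 are shared with IFITM2, so the level of each single copy is uncertain.

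Many genes of the type I interferon response rose in TFCP2L1 cells. Of the 31 tested members, 20 rose, 2 fell and 9 were not called (23 and 2 adjusted over the list alone). MX2, a GTPase that blocks viruses (chromosome 21, 41361943 to 41409390), rose from 0.203 ± 0.171 to 7.55 ± 0.430 CPM, and BST2, which tethers virus particles to the cell, rose from 0.415 ± 0.0682 to 8.06 ± 1.35 CPM. XAF1 (chromosome 17, 6755447 to 6775647) had 0 reads in the vector libraries and 218 in the TFCP2L1 libraries, which made it at least 71.9-fold higher. The list's median log2 fold change was 0.47, and camera gave an adjusted p of 3.34e-14, and adjusted p = 0.0697 with an estimated correlation. In the antigen presentation list 7 of 16 members rose and 0 fell (8 rose adjusted over the list alone), with camera's adjusted p at 0.00493 and adjusted p = 0.191 with an estimated correlation. They included the peptide transporter genes TAP1, which rose from 50.2 ± 1.12 to 73.1 ± 5.53 CPM, and TAP2, which rose from 101 ± 4.39 to 138 ± 4.09 CPM, and NLRC5, an activator of class I genes, with a log2 fold change of 0.48 ± 0.10. The immunoproteasome gene PSMB9 rose by 0.67 ± 0.16 on the log2 scale, with an edgeR adjusted p of 0.0137 that became 0.0830 without vector replicate 3 and 0.0835 without TFCP2L1 replicate 1.

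Many targets of NF-kB fell. Of 29 tested members 17 fell, 2 rose and 10 were not called (18 fell and 3 rose adjusted over the list alone). IL6 fell from 319 ± 58.2 to 106 ± 22.8 CPM, the neutrophil chemokine gene CXCL1 from 647 ± 40.2 to 254 ± 18.9 CPM, IL1A from 3.65 ± 0.589 to 1.42 ± 0.223 CPM and CCL20 from 8.96 ± 2.46 to 1.32 ± 0.211 CPM. The edgeR adjusted p of these 4 genes ran from 2.01e-08 (CXCL1) to 0.00138 (IL6). The list's median log2 fold change was -0.42, and camera gave an adjusted p of 1.08e-09, and adjusted p = 0.0942 with an estimated correlation. An antisense gene covers 20.7% of the exon bases of IL6.

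**Figure D2:**
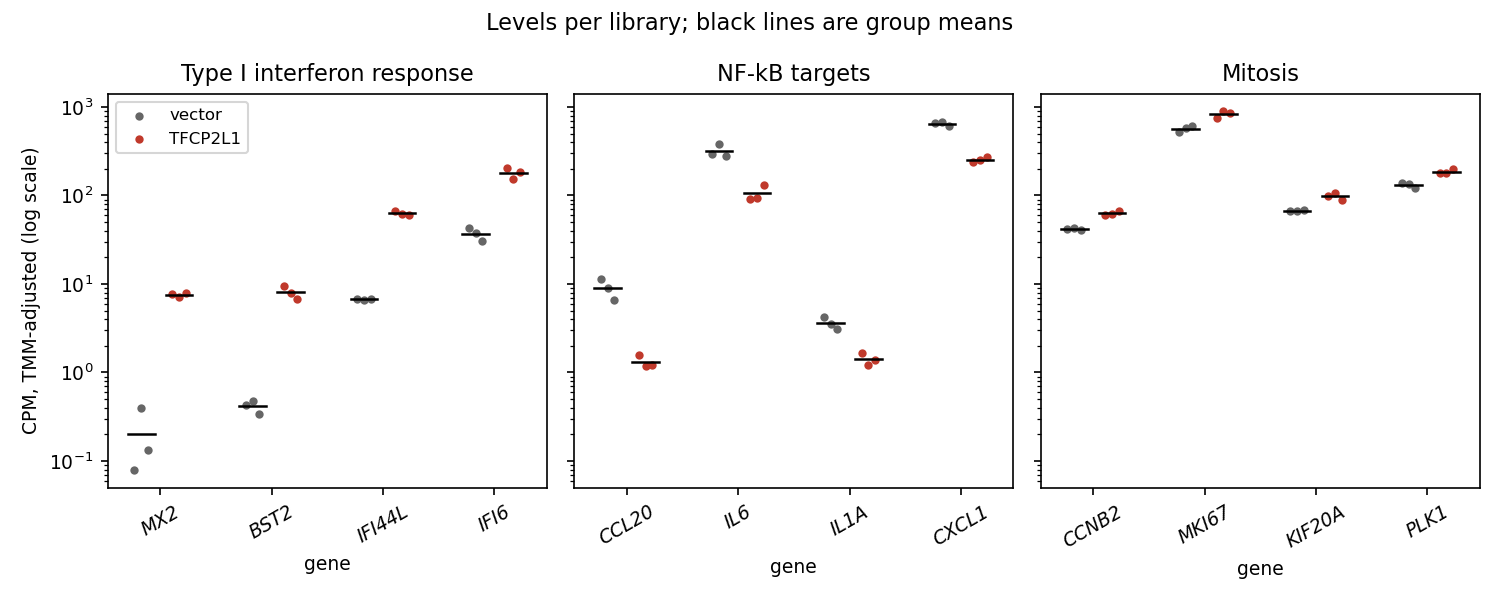
Points are single libraries and black lines group means, as TMM-adjusted CPM on a log axis, for 4 genes of each of the interferon, NF-kB and mitosis lists in vector (grey) and TFCP2L1 (red) cells. IFI44L lies near 6.71 in vector and 63.2 in TFCP2L1 libraries and CXCL1 near 647 and 254, while MKI67 moves less, from 569 to 836.

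Many genes of mitosis and some of S phase rose by a small amount. Of 41 tested mitosis genes 25 rose and 0 fell (33 rose adjusted over the list alone), with a median log2 fold change of 0.31 and camera's adjusted p at 3.34e-14, and adjusted p = 0.109 with an estimated correlation. The proliferation marker gene MKI67 rose from 569 ± 42.9 to 836 ± 70.2 CPM, the mitotic cyclin gene CCNB2 from 41.6 ± 1.41 to 63.4 ± 3.61 CPM, KIF20A from 67.1 ± 1.11 to 97.9 ± 8.12 CPM and the kinase gene PLK1 from 131 ± 7.76 to 186 ± 10.4 CPM. Among 39 S phase genes 9 rose and 0 fell (15 rose adjusted over the list alone), with camera's adjusted p at 1.08e-06, and adjusted p = 0.109 with an estimated correlation. The replication gene GINS2 rose from 13.1 ± 1.32 to 19.2 ± 0.737 CPM. E2F8 rose by 0.52 ± 0.12 on the log2 scale (edgeR adjusted p = 0.0107, and 0.0699 without vector replicate 1 and 0.0727 without vector replicate 3). Of 26 p53 targets 7 fell and 0 rose (8 fell adjusted over the list alone), with camera's adjusted p at 4.26e-05, and adjusted p = 0.0697 with an estimated correlation. The cell cycle inhibitor gene CDKN1A fell from 291 ± 5.54 to 189 ± 13.8 CPM, the apoptosis gene PMAIP1 from 548 ± 21.2 to 334 ± 30.7 CPM and the DNA repair gene DDB2 from 46.2 ± 2.92 to 23.8 ± 3.07 CPM.

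Several genes of mesenchymal transition, of cell adhesion and of epithelial identity fell. In the mesenchymal transition list 15 of 30 members fell and 3 rose (18 and 3 adjusted over the list alone), with camera's adjusted p at 6.47e-06, and adjusted p = 0.0697 with an estimated correlation. TGFBI fell from 68.8 ± 4.08 to 21.2 ± 2.19 CPM, the collagen gene COL5A1 from 34.2 ± 2.07 to 11.3 ± 1.38 CPM and TAGLN from 1.77 ± 0.575 to 0.420 ± 0.0747 CPM. Named beyond the rule, the members that rose were THBS1 (0.99 ± 0.11 on the log2 scale), CDH2 (0.49 ± 0.12) and ZEB1 (0.31 ± 0.08). VIM, SNAI1, SNAI2, TWIST1 and TWIST2 were among the 12 not called. Among 19 epithelial identity genes 5 fell and 1 rose (5 and 2 adjusted over the list alone), with camera's adjusted p at 0.00843, and adjusted p = 0.187 with an estimated correlation. The epithelial transcription factor gene ELF3 fell from 17.1 ± 1.58 to 7.15 ± 0.686 CPM, the tight junction gene CLDN1 from 632 ± 55.1 to 353 ± 42.3 CPM and the keratin gene KRT7 from 9.15 ± 0.992 to 4.69 ± 1.16 CPM. Of 22 integrins and laminins 7 fell and 1 rose (7 and 1 adjusted over the list alone; camera's adjusted p = 0.00767, and adjusted p = 0.128 with an estimated correlation), among them ITGA1 (-0.65 ± 0.08) and ITGB5 (-0.51 ± 0.08). Of 22 TGF-beta targets 7 fell and 2 rose (8 and 2 adjusted over the list alone; camera's adjusted p = 0.0292, and adjusted p = 0.277 with an estimated correlation). CDKN2B fell by 1.35 and BAMBI, a decoy receptor of the pathway, rose by 1.44 on the log2 scale. The epithelial list's call was lost without TFCP2L1 replicate 2 (adjusted p = 0.128). The TGF-beta call was lost without vector replicate 2 (0.0852) or TFCP2L1 replicate 1 (0.0589) or 2 (0.153).

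Some genes of lipid synthesis, lysosomes and hypoxia fell. Of 24 cholesterol synthesis genes 5 fell and 0 rose, and all 24 had a negative log2 fold change (12 fell adjusted over the list alone; camera's adjusted p = 2.10e-05, and adjusted p = 0.0697 with an estimated correlation). INSIG1, a regulator of sterol synthesis, fell from 183 ± 9.09 to 128 ± 10.4 CPM and LSS, lanosterol synthase, from 183 ± 2.52 to 136 ± 10.8 CPM. Of 18 fatty acid synthesis genes 9 fell and 0 rose (11 fell adjusted over the list alone; camera's adjusted p = 0.000345, and adjusted p = 0.0942 with an estimated correlation), including the desaturase gene SCD, from 1343 ± 72.9 to 1008 ± 49.4 CPM, and ACSL1, from 115 ± 10.1 to 74.5 ± 8.60 CPM. Of 33 autophagy and lysosome genes 7 fell and 1, TFEB, rose (9 and 1 adjusted over the list alone; camera's adjusted p = 0.000345, and adjusted p = 0.183 with an estimated correlation). The protease gene CTSB fell from 2311 ± 83.7 to 1341 ± 24.1 CPM and GABARAPL1 from 50.7 ± 0.850 to 25.8 ± 3.10 CPM. TFEB, a regulator of lysosomal genes, rose by 0.60 ± 0.15 on the log2 scale (edgeR adjusted p = 0.0169, and 0.0779 without vector replicate 1, 0.0840 without vector replicate 3 and 0.0760 without TFCP2L1 replicate 1). In the list of collecting duct and V-ATPase genes 5 of 16 fell and 0 rose (6 fell adjusted over the list alone; camera's adjusted p = 0.0125, and adjusted p = 0.144 with an estimated correlation), led by the proton pump subunit gene ATP6V0D2, from 99.8 ± 4.30 to 35.2 ± 1.41 CPM. The calls of ATP6AP2, ATP6V0D1 and ATP6V1C1 were each lost without vector replicate 1 or 3 or TFCP2L1 replicate 1. Of 21 hypoxia genes 6 fell and 1 rose (7 and 1 adjusted over the list alone; camera's adjusted p = 0.0309, and adjusted p = 0.180 with an estimated correlation): STC2 fell by 0.90 and NDRG1 rose by 0.67 on the log2 scale. The hypoxia call was lost without vector replicate 1 (0.0513) or 3 (0.0771) or TFCP2L1 replicate 1 (0.0782) or 3 (0.110).

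The remaining lists past camera's threshold were ERK pathway output, heat shock and histones. Of 22 ERK output genes 6 rose and 1 fell (9 and 2 adjusted over the list alone; camera's adjusted p = 0.0276, and adjusted p = 0.564 with an estimated correlation). The transcription factor gene EGR1 rose from 4.17 ± 0.836 to 15.2 ± 2.40 CPM and HMGA2 fell from 227 ± 18.9 to 153 ± 14.5 CPM. The ERK list was not called by fry (adjusted p = 0.123), and its camera call was lost without vector replicate 1 (0.0514) or TFCP2L1 replicate 3 (0.141). Of 18 heat shock genes 5 rose and 0 fell (6 rose adjusted over the list alone; camera's adjusted p = 0.00430, and adjusted p = 0.228 with an estimated correlation), led by the chaperone gene HSPA4L, from 52.1 ± 1.38 to 87.9 ± 4.96 CPM. The calls of HSPA1B, BAG3 and HSP90AA1 were each lost without vector replicate 1 or 3. In the histone list, kept as a sign of RNA selection, 4 of 9 genes fell and 1 rose (5 and 1 adjusted over the list alone; camera's adjusted p = 0.0276, and adjusted p = 0.180 with an estimated correlation). H2BC4 fell from 5.54 ± 0.460 to 2.74 ± 0.578 CPM. The histone call was lost without TFCP2L1 replicate 3 (0.102).

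**Figure D3:**
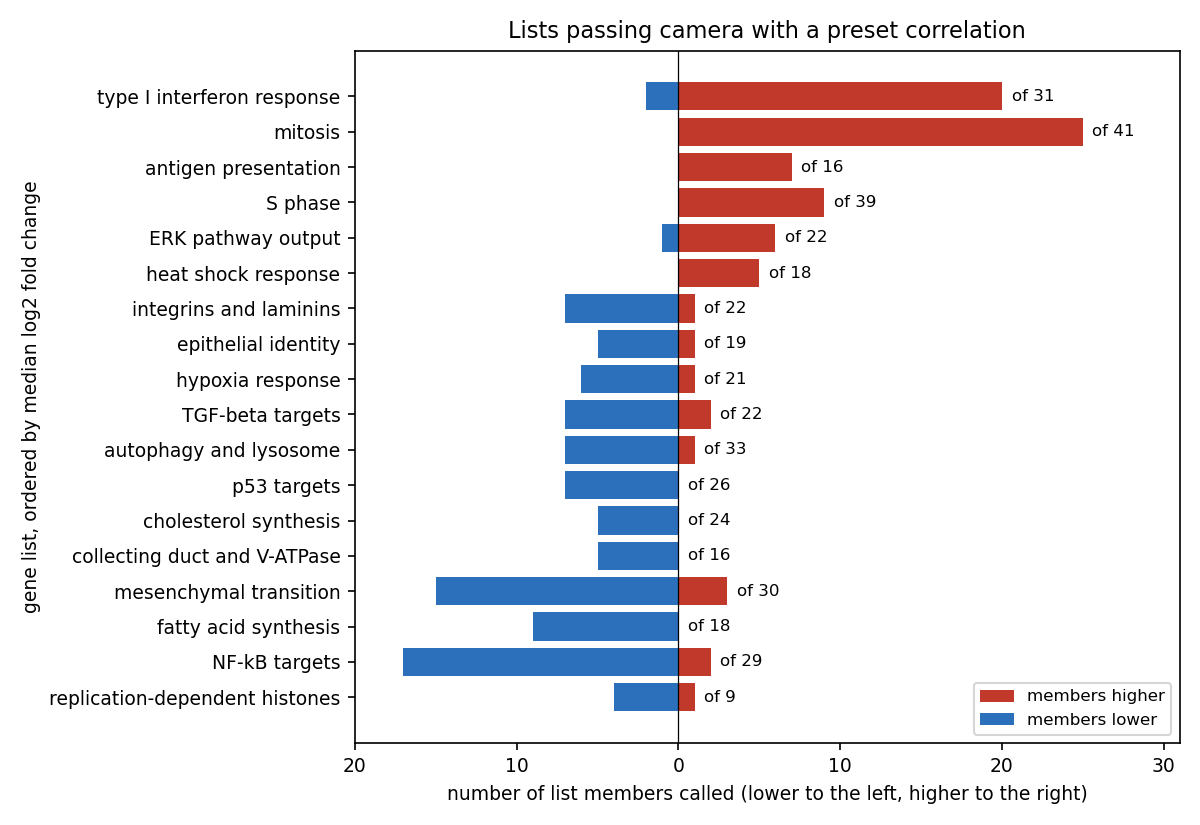
Bars count the members called higher (red, to the right) or lower (blue, to the left) by edgeR in each of the 18 lists that passed camera with a preset correlation, ordered by median log2 fold change, with the number of tested members beside each bar. Mitosis has 25 of 41 higher and NF-kB targets 17 of 29 lower, while 0 lists passed with an estimated correlation.

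Genes of thyroid differentiation were not called as a list, in which only 11 of 22 genes could be tested. Among these, PAX8 was at 544 ± 24.4 and 478 ± 47.4 CPM in vector and TFCP2L1 cells. TG was low in both, at 1.10 ± 0.361 and 1.03 ± 0.182 CPM. Of 11 tested members 3 fell and 1 rose (3 and 1 adjusted over the list alone; camera's adjusted p = 0.423), and the iodide transporter gene SLC5A5 had 0 reads in vector and 6 in TFCP2L1 libraries. RET, a member of the parafollicular C cell list and not of the thyroid list, was at 51.3 ± 1.13 and 48.0 ± 2.34 CPM (edgeR adjusted p = 0.496). YAP/TAZ targets had 5 lower and 2 higher of 21 (9 and 3 adjusted over the list alone; camera's adjusted p = 0.0976), with CCN1 at -0.61 ± 0.07. Matrix proteases and inhibitors had 6 lower and 3 higher of 24 (8 and 5 adjusted over the list alone; 0.175), with the plasminogen activator gene PLAT at -0.95 ± 0.09. Apoptosis regulators had 4 lower of 26 (5 adjusted over the list alone; 0.130) and glycolysis 5 lower of 25 (5 adjusted over the list alone; 0.269), including SLC2A3 (-0.79 ± 0.09) and LDHA (-0.38 ± 0.07). Wnt targets had 2 lower and 1 higher of 14 (2 and 1 adjusted over the list alone; 0.881), with PORCN at -0.94 ± 0.13, and the Notch pathway 2 lower and 2 higher of 16 (2 and 2 adjusted over the list alone; 0.521), with MAML2 at -0.73 ± 0.15. Naive pluripotency factors had 2 lower of 7 (3 lower and 1 higher adjusted over the list alone; 0.539), POU5F1 (-0.82 ± 0.15) among them, and the median of 0.16 and the mean of -0.09 differed in sign. NRF2 targets had 3 higher and 1 lower of 22 (4 and 3 adjusted over the list alone; 0.521), with HMOX1 at 0.52 ± 0.08 and the export pump gene ABCC3 at -1.77 ± 0.12; their median (0.03) and mean (-0.07) also differed in sign. ATF4 targets had 2 higher and 3 lower of 29 (2 and 4 adjusted over the list alone; 0.590), immediate early genes 3 and 3 of 23 (4 and 6 adjusted over the list alone; 0.744), with DUSP1 at -0.56 ± 0.10, and the unfolded protein response 0 and 1, DNAJB9, of 21 (0 and 1 adjusted over the list alone; 0.360). The DNAJB9 call was lost without vector replicate 3 (edgeR adjusted p = 0.0539). Oxidative phosphorylation had 1 of 48 higher (0 adjusted over the list alone; 0.265). Of the lists in this paragraph, fry called apoptosis regulators (adjusted p = 0.00931), matrix proteases and inhibitors (0.00356) and naive pluripotency factors (0.00162), all lower.

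Lists of RNA quality and of other cell types were not called by camera, apart from the histones above, while fry called the fibroblast markers (adjusted p = 0.0328). Ribosomal proteins had 0 of 59 members called (camera's adjusted p = 0.130) and mitochondrially encoded genes 0 of 13 (0.441), with 0 and 0 adjusted over each list alone. Nuclear-retained RNAs had 1 lower, MALAT1 (-0.42 ± 0.08), and 1 higher of 8 (3 and 1 adjusted over the list alone; 0.265). Fibroblast markers had 1 of 6 lower, FBLN1 (-0.41 ± 0.08; 1 adjusted over the list alone; 0.130), and endothelial markers 1 of 6 lower (1 adjusted over the list alone; 0.737). Leukocyte markers had ITGAX lower (-1.64 ± 0.22) and CD68 higher (0.63 ± 0.10) of 5 (1 and 1 adjusted over the list alone; 0.617). Parafollicular C cell markers had 0 of 2 tested members, SYP and RET, called (0 adjusted over the list alone). TPC1 carries a RET fusion, so RET reads do not speak to C cells. Leaving out 1 library brought 4 uncalled lists past camera's threshold: YAP/TAZ targets without vector replicate 1 (0.0450), mitochondrially encoded genes without vector replicate 2 (0.0370), oxidative phosphorylation without vector replicate 1 (0.0398) or TFCP2L1 replicate 3 (0.0222), and ribosomal proteins without vector replicate 2 (0.0395) or TFCP2L1 replicate 1 (0.00489).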

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

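The settings without the 2 libraries of highest mitochondrial share and without mitochondrially encoded genes were chosen only after the data were seen. TFCP2L1 stayed higher and past the threshold in every setting that tested it, and 0 results of named genes or lists turned their direction with a call. The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.07, -0.16 and -0.12, and vector replicate 2 correlated best with TFCP2L1 replicate 3 (0.22). With a replicate block, edgeR called 331 genes higher and 665 lower, and the hypoxia list lost its call (adjusted p = 0.0686). With no filter on low counts, the histone (0.490) and epithelial lists lost theirs. Limma on log2(FPKM + 1) with no filter called 314 genes higher, 475 lower and 88 at least 2-fold. With the filter, 91 were at least 2-fold, and 211 with a pseudocount of 0.1. A pseudocount shrinks the fold of low genes by construction. Against a 1.2-fold change, edgeR called 175 higher and 430 lower. Leaving out single libraries gave 294 to 763 genes higher, 654 to 1108 lower, 278 to 365 changed at least 2-fold and 16 to 19 lists passing. The cause was not tested. Of 147 named genes besides TFCP2L1, 135 were called. Of these, 9 to 28 lost their call without 1 library, 27 with the replicate block and 44 with log2(FPKM + 1) and no filter. The number was 11 without the 2 libraries of highest mitochondrial share and 0 with DESeq2. Over all 1692 calls, the share kept was lower: 55.7% to 85.5% without 1 library, 58.6% with the replicate block and 44.5% with log2(FPKM + 1) and no filter. DESeq2 called 861 higher and 1127 lower and included all 1692 genes called by edgeR. Library totals alone gave 910 higher and 921 lower. Without the 2 libraries of highest mitochondrial share, 546 were higher and 894 lower, with 1257 of the 1692 calls kept, and 15 lists passed. ERK output, hypoxia and histones lost their calls there. With an estimated correlation 0 lists passed camera, against 18 with the preset one and 21 by fry, and 10 had an unadjusted p under 0.05.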

Other observations

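The genes in the first 2 paragraphs were chosen after their values were seen, and the tests of cells of another line, of a stable population difference, of culture density and of leukocytes were also chosen only after the result was seen. The criteria that the length and GC result must also pass camera, and that leukocyte genes must lie below CCL3L3, were likewise added after the values were seen. The complement gene C3 fell from 1047 ± 24.1 to 285 ± 9.42 CPM (SD, n = 3; edgeR adjusted p = 1.29e-10), the acute phase gene SAA1 from 11.7 ± 0.885 to 2.96 ± 1.06 CPM and IL36RN, an antagonist of interleukin 36, from 1.99 ± 0.329 to 0.0683 ± 0.0387 CPM. The cell surface peptidase gene DPP4 fell from 276 ± 10.7 to 74.8 ± 11.2 CPM (edgeR adjusted p = 5.07e-09). Fibronectin, FN1, took 1.98% ± 0.0849 of all reads in vector cells and 1.04% ± 0.0665 in TFCP2L1 cells. TMEM52B had 76 reads in vector and 0 in TFCP2L1 libraries, at least 25.6-fold lower. The telomerase gene TERT rose by 1.54 ± 0.25 on the log2 scale (edgeR adjusted p = 0.000554).

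Members of the interferon list already abundant in vector cells did not all rise. IFIT3 was at 1004 ± 85.9 and 929 ± 121 CPM in vector and TFCP2L1 cells, OASL at 339 ± 13.5 and 343 ± 25.4 CPM, and DDX58, a sensor of viral RNA, at 401 ± 10.9 and 380 ± 39.6 CPM, none of them called. IFI44 fell from 651 ± 35.2 to 475 ± 51.6 CPM and DDX60 from 458 ± 31.7 to 306 ± 38.4 CPM (edgeR adjusted p = 0.00206 and 0.000448), while IFI44L rose. The histone genes H2BC12 (-0.72 ± 0.11), H2BC4 (-1.02 ± 0.20), H2BC21 (-1.01 ± 0.26) and H2AC6 (-0.93 ± 0.24) fell, while 9 of 39 S phase and 25 of 41 mitosis genes were called higher. With an estimated correlation, camera's adjusted p was 0.109 for both of those lists. H2BC21 lost its call without vector replicate 2 (0.0893) or TFCP2L1 replicate 1 (0.0765) or 2 (0.0637), and H2AC6 without vector replicate 2 (0.0877) or TFCP2L1 replicate 1 (0.0914).

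For the rise of the type I interferon list, cells of another line or type in the TFCP2L1 cultures could bring transcripts that vector cells lack. Only 1 gene, XAF1, itself a list member, had 0 reads in vector and 60 or more in TFCP2L1 libraries. However, 1 vector read was enough to bar a gene, as it barred TFCP2L1, so such cells are not excluded. After length and GC trends were removed the list's median was 0.489, against 0.468 before. The 314 tested neighbours of its 20 rising members, spread over 11 chromosomes, had a pooled median log2 fold change of -0.0222 ± 0.012 (bootstrap SE). This argues against gained chromosome segments around most of these members. A gain around a few of them would hardly move a pooled median, so it is not excluded. A stable difference between the vector and TFCP2L1 cells other than TFCP2L1 itself cannot be told apart from an effect of TFCP2L1. Such a difference would go with the groups, and the labels do not say whether each group came from 1 population or more. All 20 rising members were higher in each TFCP2L1 library, but the libraries of the groups did not overlap for 1688 of all 1692 called genes, so this decides nothing. An effect of TFCP2L1 on this list remains a hypothesis, untested here.

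The rise of the mitosis list, with a median of 0.315, was 0.316 after length and GC trends were removed. Without vector replicate 2 and TFCP2L1 replicate 3, the libraries with the highest mitochondrial share, it was 0.315, so these libraries did not make it. A difference in culture density may also raise mitotic genes, and it stays open, since cell density is not given in the sources used here. Of 21 YAP/TAZ targets 14 had a negative log2 fold change (camera's adjusted p = 0.0976), where a sparser culture would raise them, but no direction was set in advance and the values do not decide it. Faster division with TFCP2L1 was not tested.

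The fall of the NF-kB target list, with a median of -0.423, was -0.365 ± 0.207 (bootstrap SE) after length and GC trends were removed, and camera with the preset correlation gave an adjusted p of 1.78e-09 (before removal, adjusted p = 0.0942 with an estimated correlation). Leukocytes in the vector cultures, as a source of chemokines such as CCL3L3, were tested with 12 abundant leukocyte genes, a list written after the gene results, CORO1A among them, had been seen. The 5 tested ones had a median log2 fold change of -0.25 ± 0.314 (bootstrap SE), with LCP1 alone called lower (-1.07 ± 0.10), and SRGN (162 CPM) and LAPTM5 (156 CPM) were abundant in both groups. The other 7 were under 1 CPM in vector cells or absent from the table, among them PTPRC with 8 reads and CD53 with 0, far below CCL3L3 with 20125. Culture density and other differences between the populations were not tested for this list and stay open, as does an effect of TFCP2L1.

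For the count of called genes, 3 against 3 libraries make only 10 splits, too few for a share under 0.05. The real split called 1692 genes (3686 at an unadjusted p under 0.05), the only 1 of the 10 to call as many, and the highest of the other 9 by edgeR was 0 (at most 1121 at an unadjusted p under 0.05). Each of the other 9 put vector and TFCP2L1 libraries in both arms, so the group difference added to the spread within them. A low count was likely there whatever made the groups differ, so the splits decide nothing.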
